A study of Mus musculus with 7 samples.

How the data were processed

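Polyadenylated RNA of mouse liver endothelial cells was sequenced in 7 libraries, 3 of controls and 4 carrying a knockout (KO) of Maf, the gene of the transcription factor c-Maf. Per the labels' protocols, the cells were sorted by flow cytometry, RNA was extracted with a column kit, and libraries were made with an Illumina TruSeq kit. The protocol names an unstranded and a stranded version of that kit without saying which library had which, so the values of overlapping and antisense genes are uncertain. Nothing in the labels says that the libraries came from separate animals, and p-values then measure the spread between these libraries, which may be partly technical.

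The deposited values are raw read counts per Ensembl gene, made by the authors before deposit and not normalized. Per the submitters' processing notes, FastQC 0.11.5 and STAR 2.7.6a were used, with genome build GRCm38. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here, so it is open how reads shared by near-identical genes, such as ribosomal protein genes and their pseudogenes, were assigned. The deposited count table held 52636 genes, of which 52403 IDs matched a gene symbol and 233 did not. Coordinates come from GENCODE mouse release 21, which is on the same build.

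Groups were taken from the genotype in the labels. The lane number in the labels put control 3 and KO 3 in lane 4 and the other 5 libraries in lane 5. Total counts ran from 24772716 to 32960007 per library, and 3 counts, the limit taken for a gene with a count of 0, correspond to between 0.0872 and 0.131 CPM (each library's counts scaled to a common total). Such limits and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom lay between 13.72 and 106.3.

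Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16 at its default minimum of 10 counts and total of 15, which left 15512 genes, and were scaled by trimmed mean of M-values (TMM). Scaling factors were 0.8767 to 0.9211 in controls and 1.043 to 1.135 in KO libraries. Each gene was tested between KO and control by edgeR's quasi-likelihood F-test with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, given as mean ± SD over 3 control and 4 KO libraries. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F. The words rose and fell refer to KO against control at an adjusted p under 0.05.

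There were 43 gene lists, 33 of pathways and endothelial subtypes and 10 of markers of other cells. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Benjamini-Hochberg adjustment ran over the 41 lists with a set test. The sex-linked genes had none by design, and no T and NK cell marker was left after filtering. Where a symbol had several IDs, the ID with the most counts was used. Camera called 11 lists at adjusted p under 0.05, fry 21, of which 9 were among the 11, and camera with an estimated correlation 0, at a smallest adjusted p of 0.348.

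The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule took Maf, the 12 largest rises and the 12 largest falls among genes past the threshold with an average log2 CPM of at least 3 and no overlap between the groups' libraries, leaving out predicted and clone names and immunoglobulin and T cell receptor segments. It also took up to 4 members per list with the smallest p among those past the threshold. Other list members could be given by value where they did not pass. Some genes taken by the rule are not reported here. Alb and Ddx3y were named outside the rule, after their values were seen.

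Alternatives were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, other filters, DESeq2 1.42.0, limma-voom, a test against a 2-fold change, the lane as covariate, lane 5 alone, the replicate number as a block, removal of other cells' marker genes, and leaving out each library. The tests were tried on counts simulated for the KO against control comparison over 15512 genes with the real means, dispersions and library sizes. edgeR recovered 87 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 6.03% of its calls were unchanged genes. DESeq2 recovered 93 and 100 with 18.9% of calls unchanged genes, and limma-voom 85 and 99 with 6.6%. Only these genes were changed in the simulation, as many up as down and none at a low level. It therefore does not cover wide or unbalanced change or genes with few counts.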

Results

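The data are gene counts from sorted liver endothelial cells of mice, 3 control and 4 Maf KO libraries with 24772716 to 32960007 counts each. c-Maf is a basic leucine zipper transcription factor, and the comparison asks how liver endothelium differs in its absence. In a principal component analysis the first component held 70.82% of the variance and separated all 3 controls (-71.71 to -59.92) from all 4 KO libraries (32.02 to 68.27). The second held 8.634%.

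Maf itself, on chromosome 8 from 115682942 to 115707794 on the minus strand (GRCm38, protein-coding, ENSMUSG00000055435), was among the most strongly reduced genes. It stood at 1664, 2088 and 2147 CPM in controls 1 to 3. KO libraries 1 to 4 held 28.9, 158.9, 124.5 and 37.7 CPM, which is 1.468%, 8.083%, 6.331% and 1.918% of the control mean. The log2 fold change was -4.49 (SE 0.576, adjusted p = 0.000347). The sources used here do not say which part of the gene was deleted, so remaining reads can stem from transcript outside it.

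**Figure D1:**
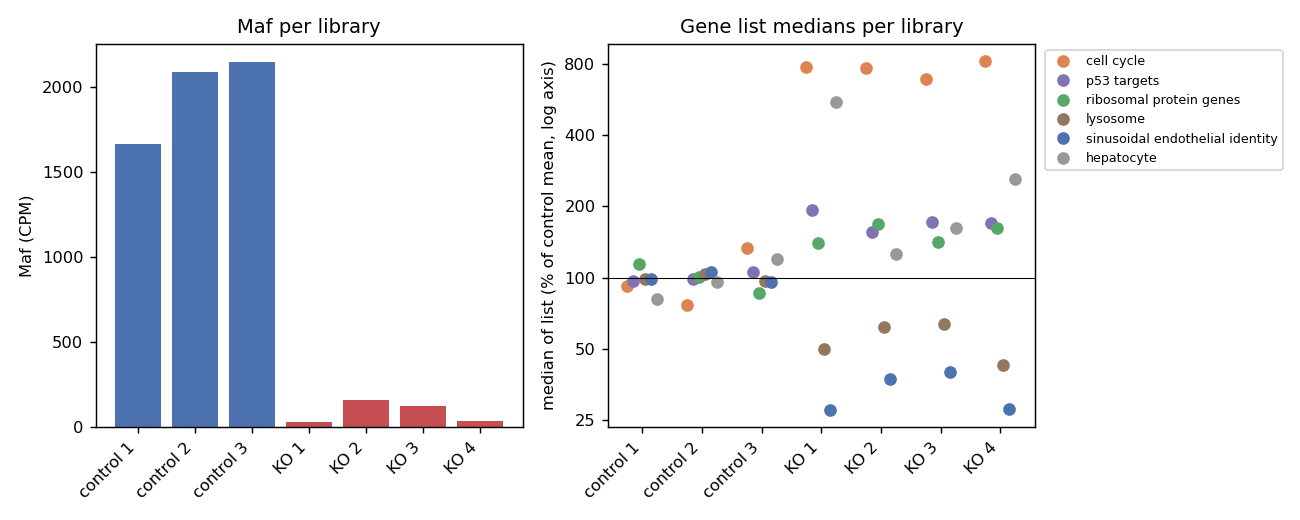
Left, Maf in CPM in each library, controls in blue and KO libraries in red: the KO bars lie between 28.9 and 158.9 CPM and the control bars between 1664 and 2147. Right, for 6 gene lists, the median over members of each library's CPM as a percentage of the control mean, on a log axis: the cell cycle list lies between 691 and 820% in KO libraries, the sinusoidal list between 27.68 and 39.98%, and the hepatocyte list between 126 and 551%.

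Expression differed widely between the genotypes. Of 15512 genes tested, 3561 rose and 3448 fell in the KO (45.18% of genes tested). Large rises outnumbered large falls: 1631 genes rose and 923 fell at least 2-fold, and 260 rose and 60 fell at least 8-fold. In 6626 of the called genes the libraries of the groups did not overlap. Of all genes tested 50.27% did not overlap, where chance gives 5.714%. With lane 5 alone, 2 controls against 3 KO libraries, 3069 genes rose and 3830 fell. Lane 4 held a single library of each group, too few for a test. The balance of rises and falls depends on scaling: 50.81% of calls were rises with TMM, 63.43% with upper-quartile factors and 76.33% with library totals, which gave 6373 rises and 1976 falls. The median log2 fold change of all tested genes was 0.0433 with TMM, 0.169 with upper-quartile factors and 0.308 with library totals, and changes below are relative to the TMM scale.

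Several genes that were nearly silent in control endothelium were expressed in the KO. Lrrc3b, a leucine-rich repeat membrane protein, had 0 counts in every control and 21.8 ± 10.3 CPM in the KO, at least 179-fold higher against a limit of 3 counts per control library. Chrm3, the M3 muscarinic acetylcholine receptor, had 5 counts over the controls and 51.1 ± 9.67 CPM in the KO, a ratio of 762 (95% exact counting interval 326 to 2350). Pdlim3, an actin-associated PDZ-LIM protein, rose from 0.256 ± 0.00674 to 67.1 ± 4.08 CPM (log2 fold change 8.01, SE 0.137, adjusted p = 7.04e-09). Gdf10, a ligand of the TGF-beta superfamily, rose 180-fold, and Pcp4l1 116-fold. Ly6c1, a surface antigen of capillary endothelium outside the liver sinusoid, rose 105-fold to 64.3 ± 20.8 CPM. The small heat shock protein gene Hspb1 rose 33.4-fold to 572 ± 202 CPM. The apelin receptor gene Aplnr rose 29.9-fold, Mcf2l, a guanine nucleotide exchange factor, 29.5-fold, and Mycn, a MYC family transcription factor, 27.6-fold from 0.959 ± 0.568 to 27.3 ± 11.8 CPM. Cd24a rose 24.0-fold and Ch25h, cholesterol 25-hydroxylase, 18.7-fold.

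The largest falls other than Maf reached 12.7- to 21.5-fold. Il13ra2, the decoy receptor of interleukin 13, fell from 67.1 ± 25.1 to 3.10 ± 2.55 CPM (log2 fold change -4.42, SE 0.602, adjusted p = 0.000479). Transporter genes were the amino acid transporter Slc7a8, 19.7-fold lower, and the zinc and manganese transporter Slc39a8, 17.9-fold lower at 444 ± 51.5 CPM in controls and 24.7 ± 17.4 in the KO. The heparan sulfate proteoglycan glypican 1, Gpc1, was 17.7-fold lower. Gpr155, Rcn3, Fcrlb, Enpp6, Ifitm10 and Flrt1 were 16.4-, 16.1-, 14.7-, 13.5-, 13.3- and 12.7-fold lower. Dnase1l3, a secreted DNase that is among the most abundant sinusoidal transcripts, fell 13.1-fold from 6154 ± 347 to 469 ± 262 CPM. In 11 of these 12 genes, Maf included, KO 2 and KO 3 both lay above KO 1 and KO 4, with Fcrlb the exception.

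**Figure D2:**
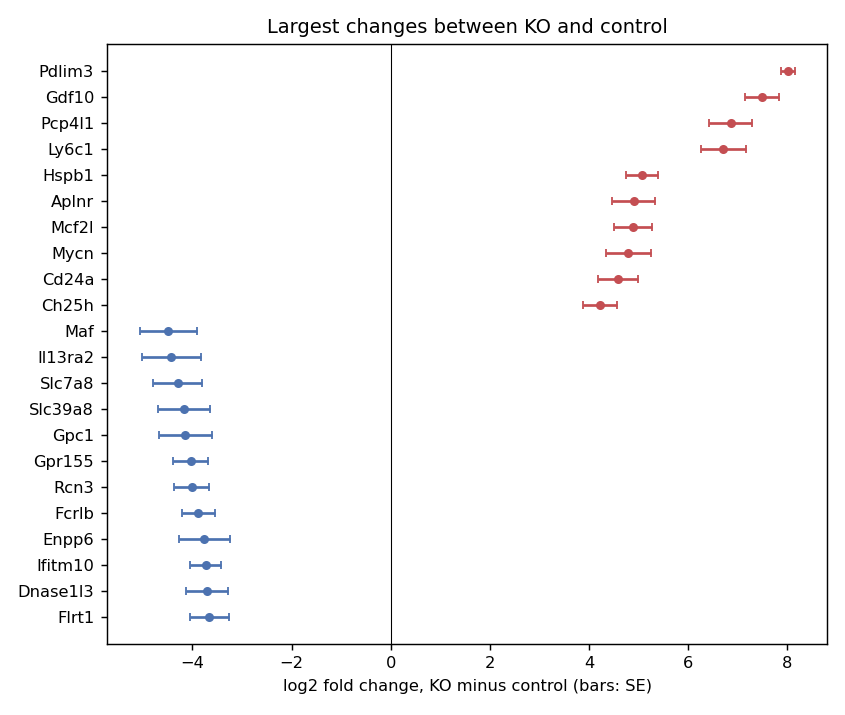
Log2 fold change (KO minus control) of 10 of the 12 largest rises (red) and the 12 largest falls (blue), with SE as bars. Lrrc3b and Chrm3 are left out because their controls held 0 and 5 counts. The rises shown run from 4.23 for Ch25h to 8.01 for Pdlim3, the falls from -3.67 for Flrt1 to -4.49 for Maf.

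Genes that mark liver sinusoidal endothelium fell as a group. Of 24 members, 18 fell, 0 rose and 6 did not pass, and 19 fell adjusted over the list alone. The median log2 fold change was -1.62 and the list's median level in the KO libraries was 27.68, 37.34, 39.98 and 27.79% of the control mean. KO 1 and KO 4, the lowest here, were highest in the hepatocyte list (550.5 and 260.1%, KO 2 and KO 3 126.2 and 162.6%). The same held for the erythroid list (723.8 and 407.7%, KO 2 and KO 3 115.7 and 109.1%). The scavenger receptor gene Stab2 fell from 5958 ± 530 to 647 ± 138 CPM (log2 fold change -3.20, SE 0.196, adjusted p = 1.00e-05). The inhibitory Fc receptor gene Fcgr2b fell 5.20-fold from 4494 ± 233 to 865 ± 191 CPM, the endocytic adaptor Dab2 3.32-fold and the C-type lectin Clec1b 2.62-fold. Gata4, a transcription factor of sinusoidal cells, did not pass, with 746 and 705 CPM in control and KO (adjusted p = 0.740), nor did Bmp2 at 2688 and 2300 CPM (adjusted p = 0.219). Camera gave an adjusted p of 1.63e-15. The call was lost with an estimated correlation, at adjusted p = 0.652 (unadjusted p = 0.0508). In lane 5 alone 18 members fell.

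Markers of continuous capillaries went both ways. Of 21 members, 8 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone. Beside Ly6c1 and Aplnr, the sialomucin gene Cd34 rose from 18.5 ± 3.54 to 277 ± 31.5 CPM (log2 fold change 3.90, SE 0.167, adjusted p = 3.58e-06) and Ly6a rose 6.61-fold to 718 ± 139 CPM. The ligand gene Apln fell 2.35-fold at 2.97 ± 0.335 CPM in controls, and the tight junction gene Cldn5 fell 2.52-fold from 701 ± 165 CPM. Plvap, of fenestral diaphragms, did not pass at 545 and 510 CPM (adjusted p = 0.581). The median log2 fold change was 0.0778 and the mean 0.763. Camera's adjusted p was 0.0543, not past the threshold, and 0.652 with an estimated correlation. It passed in each fit that left out a single library other than KO 3, at 0.0141 to 0.0471, and was 0.172 without KO 3.

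Markers of the sinusoid's zones changed in both directions. Of 8 pericentral members 2 rose and 5 fell: the receptor tyrosine kinase gene Kit fell 9.58-fold from 767 ± 144 to 80.1 ± 28.2 CPM, Cdh13 3.80-fold and the Wnt ligand gene Wnt2 3.45-fold, while the fatty acid binding protein gene Fabp4 rose 1.67-fold. Adjusted over the list alone these counts were the same, and 1 rose without control 2. Camera gave an adjusted p of 0.0391, which became 0.652 with an estimated correlation and 0.0614 without control 3. Of 6 periportal members 3 fell and 1 rose, likewise adjusted over the list alone. Msr1, Adam23 and Ntn4 fell 5.04-, 3.68- and 2.68-fold, and the ephrin gene Efnb2 rose 1.85-fold (camera adjusted p = 0.0880). Of the named rises, Fabp4 is also on the continuous capillary list and Efnb2 also on the arterial list. The periportal list passed without KO 4 (0.0382) and in lane 5 alone (0.0404), and lay between 0.0382 and 0.124 without single libraries.

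Genes of other endothelial subtypes changed in both directions. Of 14 arterial genes 8 rose and 2 fell, 3 adjusted over the list alone. Clu rose 4.78-fold from 51.8 ± 2.09 to 248 ± 17.0 CPM and the transcription factor gene Mecom 2.42-fold, while the netrin receptor gene Unc5b fell 2.36-fold. The median log2 fold change was 0.762 and camera's adjusted p 0.0543. Without control 1 the number of rises was 5. The arterial list passed without control 1 (0.0494), control 3 (0.0411), KO 2 (0.0232) or KO 4 (0.0433), and reached 0.106 without KO 3. Of 11 genes of large veins 2 rose and 4 fell, both adjusted over all genes and adjusted over the list alone, with Ackr1 2.56-fold and Selp 2.13-fold lower (camera adjusted p = 0.529). Rises numbered 0 without control 2 and 1 without control 1 or any single KO library. Of 9 lymphatic genes 1 rose and 4 fell, with the same counts adjusted over the list alone. Sema3d fell 9.40-fold, Lyve1 4.05-fold and the VEGF-C receptor gene Flt4 3.57-fold from 3483 ± 464 CPM. Lyve1 and Flt4 are also on the sinusoidal list. The camera test gave an adjusted p of 0.0880, and 0.0427 with upper-quartile factors, 0.0152 with library totals, 0.0164 without control 1 and 0.0434 without KO 1. The number of rises was 0 without control 1, KO 2 or KO 4.

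More pan-endothelial genes fell than rose. Of 13 members 7 fell and 1 rose, with the same counts adjusted over the list alone and a median log2 fold change of -0.634. The VEGF receptor gene Flt1 fell 2.73-fold from 1163 ± 79.1 to 426 ± 86.0 CPM, the angiopoietin receptor gene Tek 2.05-fold and the transcription factor gene Erg 1.65-fold. The adherens junction gene Cdh5 did not pass, at 1953 and 1504 CPM (adjusted p = 0.0935). The list's adjusted p in camera, 0.0123, became 0.652 with an estimated correlation. Of 20 endothelial transcription factors 9 rose and 6 fell, also adjusted over the list alone. The ETS factor gene Fli1 rose 1.80-fold and the homeobox gene Meis1 2.04-fold, and Tfec fell 1.59-fold (camera adjusted p = 0.848). Among 5 tested relatives of Maf, 2 rose and 2 fell, also adjusted over the list alone: Mafg was 1.98-fold lower, and Maff and Mafk 3.04- and 1.81-fold higher (camera adjusted p = 0.562), and 1 rose without control 2 or control 3, where Mafk did not pass (adjusted p = 0.0518 and 0.0521). In KO 1 to 4 Maff stood at 23.3, 17.5, 10.2 and 14.7 CPM and Mafk at 189, 142, 99.6 and 105 CPM. That is the order of the median of the dissociation stress list, given further on. Mafg, which fell, had that order too. Such matches, here and below, were looked for after the values were seen, and not all are named. How many of all genes share that order was not counted, so a match does not link a gene to stress.

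**Figure D3:**
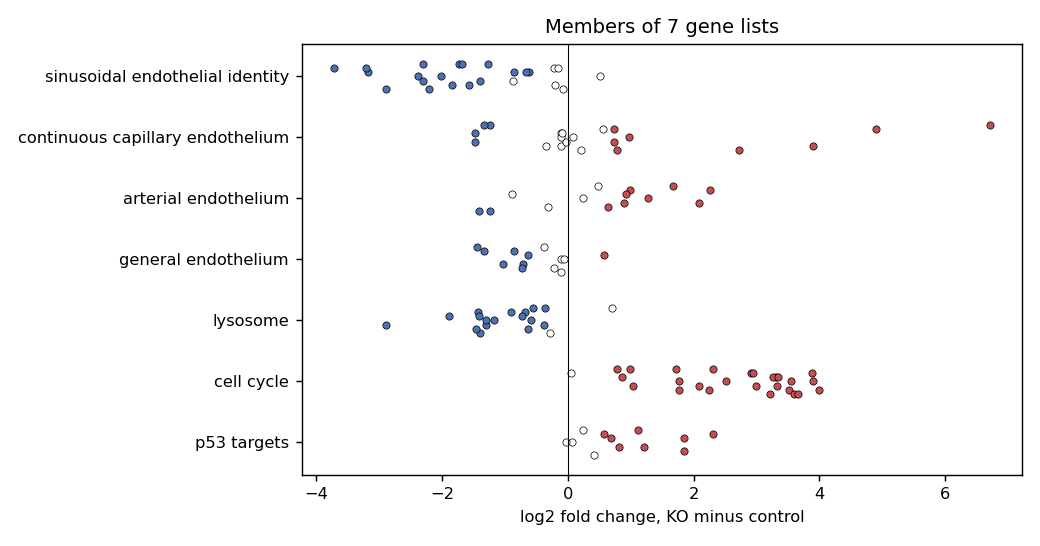
Log2 fold change (KO minus control) of each tested member of 7 gene lists. Filled points passed the test, red above 0 and blue below, open points did not, and height within a list only spreads the points. No sinusoidal or lysosomal member rose past the threshold, and no cell cycle or p53 member fell.

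Genes for signals that endothelium sends or receives changed in both directions. Of 20 angiocrine genes 4 rose and 9 fell, likewise adjusted over the list alone. The platelet-derived growth factor gene Pdgfb rose 7.27-fold from 22.3 ± 11.8 to 162 ± 24.0 CPM and the matricellular gene Ccn1 2.73-fold, while Wnt2 and Angpt2 fell 3.45- and 3.20-fold (camera adjusted p = 0.408). With library totals 7 rose. Ccn1 stood at 284, 237, 135 and 195 CPM in KO 1 to 4, the order of the dissociation stress list's median given below. Of 14 tip cell genes 8 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.149). Adrenomedullin, Adm, and Plaur were 3.16- and 2.42-fold higher, and Angpt2 and Apln 3.20- and 2.35-fold lower. Of 12 Notch pathway genes 6 rose and 3 fell, 4 adjusted over the list alone. The ligand genes Jag2 and Jag1 rose 5.43- and 1.91-fold, while the ligand gene Dll1 and Rbpj, the DNA-binding effector, fell 1.24- and 1.49-fold (camera adjusted p = 0.408). Without control 1 there were 3 rises and 5 falls, and Dll1 did not pass with library totals (adjusted p = 0.608). Of 14 genes of the BMP response 3 rose and 5 fell, likewise adjusted over the list alone. Id1 and Msx1 rose 3.13- and 7.96-fold, and the receptor gene Bmpr2 and Smad9 fell 1.82- and 2.97-fold (camera adjusted p = 0.919). With library totals, and for rises also without control 1, 5 rose, and with library totals 3 fell. Of 8 Wnt-responsive genes 4 rose and 2 fell, likewise adjusted over the list alone, with Notum 24.2-fold and Apcdd1 4.80-fold higher and Nkd1 3.32-fold lower (camera adjusted p = 0.408), and 1 fell without control 2, control 3 or KO 4. Of 8 genes that respond to shear stress 4 rose and 2 fell, with 5 rises adjusted over the list alone. Klf2 rose 1.77-fold, Nos3, the endothelial nitric oxide synthase gene, 1.41-fold and Klf4 1.501-fold, while Thbd fell 1.79-fold (camera adjusted p = 0.466). Without KO 2, 2 rose, and 1 fell without any single library other than KO 3. In KO 1 to 4 Klf2 stood at 4617, 3974, 2690 and 3313 CPM and Klf4 at 997, 949, 673 and 678 CPM, the order of the dissociation stress list's median, 242.3, 217.7, 139 and 159.3% of the control mean. Klf4 did not pass without control 1 (adjusted p = 0.0762), control 3 (0.0665) or KO 2 (0.0535), nor, with Thbd (0.0833), without control 3 and KO 1 together (0.103). Of 8 genes of caveolae and fenestrae 3 rose and 0 fell, with 1 fall adjusted over the list alone. Cav1 and Cavin1 rose 1.95- and 1.86-fold (camera adjusted p = 0.439), and 1 fell without KO 3.

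Matrix genes showed no common direction. Of 16 basement membrane genes 5 rose and 3 fell, with 6 rises adjusted over the list alone. The heparan sulfate proteoglycan gene Agrn rose 1.64-fold and Nid2 1.33-fold, and the laminin genes Lamb2 and Lama4 fell 1.41- and 1.39-fold (camera adjusted p = 0.853). Rises numbered 2 without control 2 and 3 without control 1, control 3, KO 3 or KO 4 or in lane 5, and 1 fell without control 2 and 0 with library totals. Lama4 did not pass without control 2 (adjusted p = 0.0555), without control 3 and KO 1 together (0.05003) or with library totals (0.125), nor did Lamb2 with library totals (0.0782). Of 17 genes of fibrillar matrix 3 rose and 3 fell, likewise adjusted over the list alone. Fibrillin 1, Fbn1, rose 5.02-fold from 21.7 ± 7.63 to 109 ± 14.2 CPM, while Loxl2 and Dcn fell 2.43- and 3.48-fold (camera adjusted p = 0.848). Without control 2, 1 rose, Dcn did not pass without control 3 and KO 1 together (adjusted p = 0.0701), and without control 3 the list's median log2 fold change of -0.97 became 0.444. Control 3 was highest in fibroblast transcripts, with Col3a1 at 54.08 CPM against 0.6917 and 7.078 in the other controls.

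Cell cycle genes rose almost without exception. Of 27 members 26 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 2.95. Mcm3 did not pass (log2 fold change 0.0559, adjusted p = 0.622). The mitotic kinesin gene Kif23 rose from 3.38 ± 1.05 to 40.9 ± 2.83 CPM (log2 fold change 3.60, SE 0.187, adjusted p = 5.87e-06), the spindle checkpoint kinase gene Bub1 14.9-fold, the mitotic kinase gene Plk1 7.72-fold, and Mcm5, of the replicative helicase, 3.41-fold. The list's median level was 778, 769.5, 691.2 and 820.1% of the control mean in KO 1 to 4. Camera gave an adjusted p of 2.59e-41, and 0.348 with an estimated correlation. In lane 5 alone 26 rose. Targets of p53 rose in 8 of 12 members and fell in 0, also adjusted over the list alone, among them Phlda3 4.98-fold, Eda2r 3.59-fold and Aen 2.18-fold. Mdm2 did not pass at 64.9 and 76.6 CPM (adjusted p = 0.145). The p53 list had a camera adjusted p of 4.73e-05, which became 0.652 with an estimated correlation. Hepatocyte, platelet and megakaryocyte, and immediate-early stress transcripts, given further on, also rose in part, and erythroid markers had a median log2 fold change of 1.68 with none past edgeR's test.

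Ribosomal protein genes rose by modest and similar factors. Of 81 genes 65 rose and 0 fell, 68 adjusted over the list alone, with a median log2 fold change of 0.636 and quartiles of 0.474 and 0.797. Rpl10a rose 2.71-fold from 78.8 ± 8.85 to 214 ± 26.7 CPM, and Rpl39, Rps26 and Rpl32 2.40-, 2.34- and 2.33-fold. Many of these genes have processed pseudogenes, and how shared reads were counted is not given. By camera the adjusted p was 2.27e-12, and it became 0.652 with an estimated correlation. In lane 5 alone 55 rose, and 50 to 67 rose when single libraries were left out. Against a 2-fold change, 1 rose.

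Lysosomal genes fell. Of 19 members 17 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -0.899. Cathepsin L, Ctsl, which is also on the sinusoidal list, fell 7.41-fold from 2180 ± 114 to 294 ± 114 CPM (adjusted p = 8.20e-05). Cathepsin D, Ctsd, fell 3.70-fold from 596 ± 37.3 CPM, the hexosaminidase gene Hexa 2.65-fold and the acid glucosidase gene Gaa 2.62-fold. The genes that did not pass were Cd63 (adjusted p = 0.137) and Lipa (adjusted p = 0.165). In camera the adjusted p of 1.56e-08 became 0.652 with an estimated correlation. With library totals 14 fell and 1 rose, and against a 2-fold change 4 fell.

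Markers of other cells and genes of the dissociation stress list also differed between the groups. Whether handling or the genotype raised the stress genes was not tested. Of 18 hepatocyte markers 10 rose and 0 fell, 12 adjusted over the list alone. Alb, the most abundant, stood at 203, 180.6 and 182 CPM in controls and at 879.1, 228.9, 249.7 and 416.2 CPM in KO 1 to 4, and Cps1 and Cyp3a11 rose 4.86- and 2.81-fold. Alb passed narrowly (adjusted p = 0.0421) and did not pass without control 1 (0.0865), control 2 (0.117), control 3 (0.101) or KO 4 (0.0748), in lane 5 alone (0.0634), with the lane as covariate (0.0611), or with DESeq2 (0.0861) or limma-voom (0.0510). Cps1 did not pass without control 2 (adjusted p = 0.0539) or with limma-voom (0.0512). The list's camera adjusted p of 0.0475 became 0.840 with an estimated correlation, 0.0779 without control 1, 0.101 with upper-quartile factors, 0.202 with library totals and 0.0608 with the lane as covariate. Rises numbered 3, 1 and 3 without control 1, 2 or 3, 5 without KO 4, 6 with the lane as covariate and 3 with limma-voom. Of 13 immediate-early and heat shock genes induced by tissue dissociation 5 rose and 0 fell, 9 adjusted over the list alone. Atf3 and Nr4a1 rose 6.62- and 5.87-fold, with Atf3 at 1283, 913.6, 382.7 and 497.8 CPM in KO 1 to 4. Camera's adjusted p of 0.00816 became 0.698 with an estimated correlation. The number of rises was 10 without KO 3 or without a filter, 8 with the lane as covariate, 9 with upper-quartile factors or DESeq2, 11 with library totals and 2 against a 2-fold change. Of 14 stellate cell and fibroblast markers 9 fell and 0 rose, also adjusted over the list alone, including Rgs5, Des and Ecm1, which fell 4.17-, 3.68- and 2.05-fold. Ecm1 was at 173 ± 11.7 CPM in controls. Camera's adjusted p of 0.00781 became 0.652 with an estimated correlation and 0.0644 in lane 5 alone.

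Most leukocyte and blood cell markers did not pass. Of 13 Kupffer cell and macrophage markers 1 rose and 1 fell, 0 and 1 adjusted over the list alone: Cd68 rose 1.95-fold and C1qb fell 3.68-fold from 42.5 ± 17.3 CPM (camera adjusted p = 0.387). Without KO 2, 5 fell at a camera adjusted p of 0.0428, and without control 1, 3 fell, and the rise was lost without control 1 (adjusted p = 0.129), control 3 (0.129), KO 1 (0.0802), KO 2 (0.0785) or KO 4 (0.0889), and with limma-voom (0.0618). Of 5 B cell markers 2 fell, 1 adjusted over the list alone, among them Ighd, under 1 CPM on average in controls (camera adjusted p = 0.408), with 4 falls without control 3, 0 without control 1 or KO 4, and 1 without control 2, KO 1 or KO 3. Ighd did not pass without control 1 (adjusted p = 0.337), KO 1 (0.0772), KO 3 (0.0710) or KO 4 (0.109), with upper-quartile factors (0.0577), library totals (0.0741) or the lane as covariate (0.0544), or with DESeq2 (0.0538) or limma-voom (0.0762). Of 5 dendritic cell markers 3 fell, also adjusted over the list alone, with Irf8 2.11-fold and Bst2 1.60-fold lower (camera adjusted p = 0.149). Bst2 is also on the interferon response list and stood at 520 ± 83.3 CPM in controls, so its fall cannot be assigned to dendritic cells. No marker of cholangiocytes (3 tested), neutrophils (4) or erythroid cells (5) passed edgeR's test, at camera adjusted p of 0.919, 0.875 and 0.408. At an unadjusted p under 0.05 they numbered 1, 0 and 3, and DESeq2 called 0, 0 and 1 and limma-voom 0 in each list. Without control 1, 1 neutrophil marker fell, and 2, 2 and 3 erythroid markers rose without control 1, KO 2 and KO 3. With library totals 3 erythroid markers rose. Of 5 platelet and megakaryocyte markers 4 rose, also adjusted over the list alone, including Itga2b 2.34-fold from 12.6 ± 1.38 CPM. Pf4 did not pass at 4.90 and 3.31 CPM (adjusted p = 0.103, camera adjusted p = 0.0927), and 1 marker fell without control 3. Of 7 mitochondrially encoded genes 0 passed edgeR's test, also adjusted over the list alone, at an unadjusted p under 0.05, with DESeq2 and with limma-voom, with camera adjusted p = 0.883. Among them 1 rose without KO 3 or in lane 5 alone, and 2 with library totals. Every library expressed Y-linked genes, with Ddx3y between 62.64 and 99.05 CPM, and Xist did not exceed 2.00 CPM. Of the 5 sex-linked genes Ddx3y fell 1.38-fold and 4 did not pass, and Ddx3y did not pass with library totals (adjusted p = 0.0829).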

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

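The tests of hepatocytes, erythroid cells, platelets and megakaryocytes, and of cells that kept Maf were chosen only after the result was seen. Chance as the source of the calls was examined by fitting all 35 splits of the 7 libraries into 3 and 4. Rises and falls in a split are those of its 4 libraries against its 3. For genes that rose, 1 of the 35 splits, the real one, gave as many as 3561, and the highest of the others gave 2573. For genes that fell, 1 split, the real one, gave as many as 3448, and the highest other gave 1508. The real split thus ranked first for both counts. With 35 splits no share can fall below 1 of 35, so the rank argues against chance without excluding it. It does not separate genotype from another difference between the same libraries. The highest other split took KO 1, KO 2 and KO 4 as its 3 libraries, against KO 3 and the 3 controls. Its 2573 rises were thus genes lower in those 3 KO libraries, and its 1508 falls genes higher in them.

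Outlying KO libraries were sought by Dixon's test in 149 genes, 42 list medians and 6 library measures. The test used the critical value for 4 libraries and so covered the KO group alone, not the 3 controls. It picked out 10 of 197, where chance gives about 9.85. KO 3 was lowest in Id1 (177 CPM, the others 280 to 292), Itga2b (23.7 against 31.0 to 31.8) and Mvd (8.18 against 9.26 to 9.38). KO 4 was highest in Kif23 (45.1 CPM, the others 38.8 to 39.8) and Mcm5 (80.8 against 68.2 to 70.3) and lowest in Nid2 (37.8 against 41.6 to 42.3). KO 2 was lowest in Chrm3 (36.7 CPM, the others 54.7 to 57.1). KO 1 was highest in Ifit1 (32.5 CPM, the others 23.2 to 24.2) and in the arterial list's median (204% of the control mean, the others 142 to 152%), and lowest in the median of the unfolded protein response (76.8%, the others 95.8 to 97.7%).

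The first pattern is the rise of 26 of 27 cell cycle genes, and if other dividing cells in the sort were the source, their own abundant genes had to rise. A set of 10 genes expressed mainly in leukocytes had a median log2 fold change of -0.674 (quartiles -0.789 and -0.271), which argues against leukocytes. The hepatocyte and erythroid lists were a median 4.14- and 5.07-fold higher in KO 1 than in KO 2 (quartiles 3.08 and 5, and 4.99 and 6.82), while the cell cycle list had a ratio of 1.001 (0.955 and 1.05), which argues against both. Under DESeq2 size factors, upper-quartile factors and library totals at least 26 members rose. These scalings shifted all genes too little to change that count, so it does not test scaling. The list's median was 2.92 to 3.21 under them, against 0.02 to 0.308 over all tested genes. Scaling moves all genes alike, so it does not account for this excess over other genes. Platelet and megakaryocyte markers had a median log2 fold change of 2.11 and a ratio of 1.15 between KO 1 and KO 2, too near 1 to decide, and such cells stay open, as do a hypothesis that loss of Maf goes with proliferation of the endothelial cells and, untested, a different yield of dividing endothelial cells in the sort.

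The second pattern is the rise of 65 of 81 ribosomal protein genes. Under other scalings at least 63 rose, with medians of 0.613 to 0.900 against 0.02 to 0.308 over all tested genes. Only DESeq2 size factors lowered the median of all genes, from 0.0433 to 0.02, so a larger downward shift was not tested. Scaling moves all genes alike, so it does not account for the excess over other genes. A set of 297 other genes matched on exon length (median 2037 bases against 1739), GC content (50.8% against 50.9%) and level (average log2 CPM 7.28 against 7.54) had a median log2 fold change of -0.0486 (quartiles -0.520 and 0.306), with 58 rises and 96 falls. This argues against level, and against length and GC content as measured. Length was that of all annotated exons of a gene merged, and GC content that of its longest annotated transcript. The length of the transcripts expressed was not matched. That length and reads shared with processed pseudogenes were not tested and stay open, as does the genotype.

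The third pattern is that KO 2 and KO 3 kept more Maf and more sinusoidal transcripts than KO 1 and KO 4. If cells with a control level of Maf were the whole source, Maf and the sinusoidal genes would need the same share of such cells. Relative to KO 1, Maf needs 6.71% in KO 2 and 4.94% in KO 3. The 18 fallen sinusoidal genes need a median of 10.4% (quartiles 8.10 and 14.7) in KO 2 and 14% (8.70 and 23.1) in KO 3, above Maf's share. The 922 genes other than Maf that fell at least 2-fold need a median of 10.9% in KO 2 and 13.8% in KO 3, also above it. Their wider quartiles, 3.25 and 17.9 in KO 2 and 3.59 and 25.7 in KO 3, still hold Maf's share. On that spread, cells with a control level of Maf stay open, as do, untested, cells with partly reduced Maf, and differences in hepatocyte, erythroid and stress transcripts between the KO libraries.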

How the results depend on the processing

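Leaving out control 3 and KO 1 together was an alternative chosen after seeing the data, as were the list counts under each alternative. Of the 161 genes taken by the rule or named in the text that rose or fell, Maf apart, none turned sign under an alternative that gave it a value. That was 139 genes with other cells' markers removed, 156 with the 1 CPM filter, 160 without KO 2 and 161 otherwise. Of genes with a value, a test against a 2-fold change dropped 86, and each other alternative at most 9. Maf kept its call throughout, with a log2 fold change between -4.95 and -4.13.

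Calls numbered 6373 higher and 1976 lower with library totals, because the scale shifts, and 646 and 363 against a 2-fold change, by the test's construction. Without single libraries they ran from 2379 to 3769 higher and from 2584 to 3930 lower, and of the 7009 calls of all libraries between 69.18% and 95.71% kept their call and direction. DESeq2 kept 94.56% and limma-voom 95.23%. Without control 3 and KO 1 there were 2533 and 2615, with 17 sinusoidal and 16 lysosomal falls and 26 cell cycle, 53 ribosomal protein and 8 p53 rises.

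The sinusoidal set test lost its call with an estimated correlation (adjusted p = 0.652), and otherwise lay between 1.77e-28 and 0.00336, without single libraries between 5.77e-17 and 7.94e-15. The capillary set test passed with fry (0.00943), without a filter (0.00308), without control 3 and KO 1 (0.0207), and lay between 0.0141 and 0.172 without single libraries. The cause was not tested.

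Among genes short of the threshold the sign of the log2 fold change turned, with no cause tested. With upper-quartile factors it was 0.0421 for Gata4, 0.0861 for Pes1 and 0.0280 for Plvap, and with library totals 0.182, 0.226 and 0.165, and 0.0363 for Bmp2. Col3a1 reached 0.173 in lane 5, 0.0335 with the replicate block and 1.03 without control 3 and KO 1, where Pes1 reached 0.0479, and Mcm3 -0.0119 in lane 5. Without single libraries Gata4 ran from -0.244 to 0.0382, Pes1 from -0.0833 to 0.0333, Col3a1 from -2.21 to 0.997 and Xist from -1.92 to 0.0825.

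Correlations between libraries neither established nor excluded a pairing by replicate number. Deviations of same-numbered libraries correlated at -0.0133, 0.162 and 0.0674, and those of differently numbered ones at -0.176 to 0.0781. KO 2 and KO 3 correlated best with the control of their own number, and KO 1 did not. With the replicate block on 6 libraries 2448 genes rose and 2607 fell, against 2720 and 2833 in the same 6 libraries without it. The capillary test then gave 0.00536 and 0.0433, the arterial 0.0438 and 0.0433, and the periportal 0.0138 and 0.0382. The replicate block took the lymphatic (0.0295 against 0.0872) and tip cell (0.0381 against 0.0872) lists past the threshold. Depth limits genes under about 0.1 CPM.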

Other observations

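Immune and vascular defence genes changed in part. Of 14 complement and coagulation genes 6 fell and 2 rose, also adjusted over the list alone. The complement inhibitor gene Cd55 fell 3.93-fold, the tissue factor pathway inhibitor gene Tfpi 3.44-fold and C1ra 1.69-fold. Camera's adjusted p of 0.00475 became 0.652 with an estimated correlation and 0.0574 without control 3 and KO 1 together. Of 15 genes of inflammation and leukocyte adhesion 5 rose and 3 fell, also adjusted over the list alone, with Tnf and E-selectin, Sele, 9.96- and 5.27-fold higher and P-selectin, Selp, 2.13-fold lower (camera adjusted p = 0.466). With library totals 7 rose and 1 fell. Tnf stood at 101.2, 45.3, 20.5 and 40.1 CPM in KO 1 to 4, and Sele at 93.0, 80.7, 22.4 and 32.5 CPM. Both had the order of the dissociation stress list's median, which was also highest in KO 1. Of 18 interferon response genes 5 rose and 2 fell, also adjusted over the list alone, with Oas2 14.7-fold higher and Ifit1 not past the threshold at 18.2 and 25.8 CPM (adjusted p = 0.0545, camera adjusted p = 0.317). With library totals 10 rose, and without control 2, 1 fell. Of 7 genes of class II antigen presentation 3 fell, also adjusted over the list alone, with Cd74 2.18-fold lower from 21.3 ± 3.98 CPM (camera adjusted p = 0.229).

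Metabolic genes changed in both directions. Of 15 glycolytic genes 6 rose and 2 fell, with 7 rises adjusted over the list alone. The hexokinase gene Hk2 rose 2.80-fold from 6.89 ± 1.42 CPM and Gapdh 1.43-fold (camera adjusted p = 0.229, and 0.0366 with library totals). Falls numbered 0 without control 1 and 1 without control 2, KO 1, KO 2 or KO 4. Of 18 genes of cholesterol synthesis 4 rose and 3 fell, also adjusted over the list alone, with Srebf2 1.65-fold and Sc5d 2.23-fold lower and Mvd 1.69-fold higher (camera adjusted p = 0.980, with camera's direction down and fry's up), and the list's median of 0.000862 turned to -0.0225 with DESeq2 size factors. Without control 3, or in lane 5 alone, 2 rose. In the unfolded protein response 1 gene of 13 rose and 4 fell, also adjusted over the list alone. Hspa5, the chaperone BiP, rose 2.87-fold from 600 ± 7.84 to 1725 ± 638 CPM while Calr, Herpud1 and Dnajb9 fell 1.61-, 1.41- and 1.52-fold (camera adjusted p = 0.646). With library totals 5 rose and 2 fell, the list's median of -0.0869 became 0.180, and Herpud1 did not pass (adjusted p = 0.0807). Without control 1 or KO 3, 2 rose.

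The rise of Mycn and of ribosomal protein genes led to a hypothesis, formed from these data, that ribosome production as a whole may be higher in the KO. A list of 20 ribosome biogenesis genes was written after those rises were seen and before its members' values were. Of these, 19 rose and 0 fell, with a median log2 fold change of 0.776. Nop58, Nhp2 and Nop56 rose 2.64-, 2.56- and 2.48-fold, and Pes1 did not pass (adjusted p = 0.766). The result is consistent with the hypothesis and does not separate it from the higher level of cell cycle genes or of dissociation stress transcripts. The members named were picked after their values were seen, as was Myc, which was 10.4-fold higher, at 22.6, 28.1 and 21.4 CPM in controls and 312, 294, 152 and 241 CPM in KO 1 to 4 (log2 fold change 3.38, SE 0.257, adjusted p = 2.62e-05). KO 3 was the lowest KO library in Myc, Mycn and 18 of the 19 raised genes. It was also lowest in the median of the dissociation stress list. That median was 242.3, 217.7, 139 and 159.3% of the control mean in KO 1 to 4, the order also seen in Myc and Mycn.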
